A study of Mus musculus with 6 samples.

How the data were processed

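RNA was measured in LSK cells (lineage-negative, cKit-positive, Sca1-positive bone marrow cells) of 3 WT and 3 N1IC mice. Per the labels' protocols, mice aged 21 days received 3 injections of polyIC at 20 mcg per g of body weight, and cells were sorted 2 weeks after the last one. The labels' treatment text names floxed Ncstn alleles, while the genotype, source and series labels name N1-IC; the groups follow the genotype labels. Total RNA was amplified with the Nugen Ovation system and labelled with biotin, per the labels' protocols, and amplification from small amounts of RNA can widen the spread of dim genes. The labels describe each sample as coming from a mouse, but do not say which mice were littermates of which.

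The values are probe set intensities on a linear scale, which the authors made with RMA (background correction, normalization and summary over probes), per the submitters' processing notes. The version and settings of RMA are not given in the sources used here. That the deposited intensity values are linear was settled from their range, and log2 was taken before any test. The scanner files and detection calls were not used here, so no level is called absent, and dim probe sets carry compressed fold changes. No batch or scan date was used, since the labels give none.

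Of 45101 probe sets, 34945 had 1 gene symbol in the platform's annotation, 932 had several, 9160 had none and 64 were controls. Symbols were updated by gene ID through the RefSeq genes of assembly GRCm38.p6, which hold 34741 of the probe sets with 1 symbol. Each of 18193 genes was represented by the probe set with the highest mean over all 6 arrays. No pair of arrays held identical values. Pearson's correlation over all probe sets other than controls was between 0.985 and 0.989 for pairs of WT arrays, between 0.99 and 0.992 for pairs of N1IC arrays, and between 0.968 and 0.975 across the groups; probe sets are not independent replicates. The first principal component held 57.9% of the variance and separated the groups, and the next, with 15.4%, set WT replicate 1 apart from the other arrays.

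N1IC was compared with WT by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 4 residual and 2.05 prior degrees of freedom. A log2 fold change is the N1IC mean minus the WT mean. Data were read with the R package data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. On simulated data with 200 genes changed among 18193, this test recovered 56% of the genes changed by a log2 fold change of 1 and 85% of those changed by 2, and called 1 unchanged gene. The real comparison called 2144 genes. The p needed to pass depends on the share of genes changed, so these rates need not hold for it.

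From textbook knowledge, 23 gene lists were fixed before the data were examined, 21 for testing and 2 for sex checks. They were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 21 lists, and members were also counted with p adjusted over the list alone. Some members, such as Tcf7, Ly6a and Lck, were not analysed here. Genes named in the text followed a rule fixed at the same time. It took the 15 genes with the largest rise and the 15 with the largest fall among those past the threshold without overlap between the groups. Sex-linked check genes, genes on the Y chromosome and genes with only a provisional symbol were skipped. From each list it took up to 6 members called over all genes or over the list alone, by smallest p, or else 3 bright members, and always Notch1, Ncstn, Hes1 and the sex check genes. Genes outside the rule are said to be named after their values were seen.

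The alternatives tried were the replicate number as a block, sex as a covariate, a repeated quantile normalization, median centring, and only the brighter 60% or 40% of genes. Further ones were the mean of all probe sets of a gene, each probe set on its own, an intensity trend or robust prior in eBayes, array weights, removal of genes of the X and Y chromosomes, other thresholds, and leaving out each array. For lists, camera with an estimated correlation and fry were added. A fit with female mice only was chosen after the data were examined. It and the fit with sex as a covariate both set the N1IC arrays against WT replicate 2, the only WT female. Calls gained or lost in these fits therefore do not measure an effect of sex.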

Results

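Expression was measured with 1 Affymetrix array per sample in bone marrow cells sorted as lineage-negative, cKit-positive and Sca1-positive. This fraction, called LSK, holds hematopoietic stem cells and early multipotent progenitors. The 6 samples came from 5-week-old mice, 3 labelled WT and 3 labelled N1IC. WT mice carried the Mx1-cre transgene, in which polyIC induces the recombinase Cre. N1IC mice carried it together with a Cre-dependent allele of N1-IC, the intracellular and active part of the receptor Notch1. Median intensity over all probe sets lay between 89.0 and 92.4 on the 6 arrays, and the small number of arrays limits the precision of every value below. Values are given as log2 intensity, and 18193 genes were tested with 1 probe set each.

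The sex labels are unbalanced, with 2 males and 1 female among the WT mice and 3 females among the N1IC mice. Levels of Xist, the RNA expressed from the inactive X chromosome, matched the labels on all 6 arrays. Xist lay between 12.61 and 12.94 on the 4 female arrays and between 6.38 and 6.51 on the 2 male arrays. On their brightest probe sets, the Y-linked genes Eif2s3y, Kdm5d and Uty lay between 2.87 and 3.55 on the female arrays and between 7.25 and 11.47 on the male arrays. None of 6 X-linked genes with a partner on the Y chromosome passed the limma test between the groups, and Kdm6a had the highest log2 fold change among them, 0.52.

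**Figure D1:**
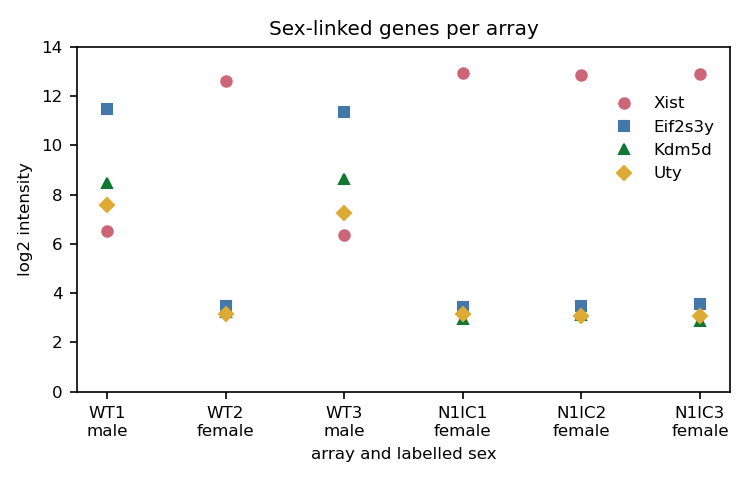
Log2 intensity of Xist and of the Y-linked genes Eif2s3y, Kdm5d and Uty (vertical axis) on each array, with the labelled sex (horizontal axis); each point is 1 array. Xist lies at 12.61 or above on the 4 female arrays, and the Y-linked genes lie at 7.25 or above only on the 2 male arrays.

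The comparison of N1IC with WT asks how active Notch1 changes gene expression in LSK cells. Among the fixed gene lists, 11 of 13 Notch target genes and 12 of 21 T-lineage genes were higher in N1IC, and 18 of 25 stem cell, 13 of 19 megakaryocyte, 11 of 27 granulocyte-macrophage and 7 of 15 B-lineage genes were lower. With an estimated correlation between genes, the camera test kept its call for the Notch target list alone (adjusted p = 0.0316 with an estimated correlation) and lost the others, at 0.148 for T-lineage, 0.107 for stem cell, megakaryocyte and B-lineage, and 0.447 for granulocyte-macrophage genes. This form of camera also uses only the 4 residual degrees of freedom, so a lost call need not mean correlated genes. Il2ra, the alpha chain of the interleukin 2 receptor, was 113-fold higher in N1IC, at 13.08 ± 0.09 against 6.26 ± 0.41 in WT (SD, n = 3). Ptcra, the pre-T cell receptor alpha chain, was 109-fold higher, at 11.61 ± 0.28 against 4.84 ± 1.04. In the other direction, the B cell transcription factor Ebf1 was 45.6-fold lower, at 5.62 ± 0.61 against 11.13 ± 0.43, and the platelet chemokine Pf4 was 33.4-fold lower, at 7.07 ± 0.65 against 12.13 ± 0.32. By limma with Benjamini-Hochberg adjustment, the adjusted p was 0.000107 for Il2ra, 0.0015 for Ptcra, 0.00103 for Ebf1 and 0.00112 for Pf4.

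Over all genes, 632 were higher and 1512 were lower in N1IC at the adjusted threshold, of which 289 and 768 differed at least 2-fold. In all 2144 of them the 3 N1IC arrays lay wholly above or wholly below the 3 WT arrays. This held for 32.8% of all genes tested, where chance gives 10%. With sex as a covariate the counts were 116 higher and 333 lower. All N1IC mice are female and WT replicate 2 is the only WT female, so this fit sets N1IC against that array alone. A fit with female mice alone, a setting chosen after the data were examined, makes the same comparison. Fewer calls in these fits therefore do not measure an effect of sex. All 2144 genes kept their direction in both fits, which was fixed in advance because the groups do not overlap for any of them. Of the 30 genes with the largest changes, 5 lost their call with sex as a covariate, namely Khdc1a, Cd3e, Mpzl2, Rab7b and Sdc1, at log2 fold changes of 7.39, 3.39, 3.31, -4.98 and -4.10 in that fit. Leaving out WT replicate 3 gave 332 higher and 835 lower, the lowest counts among the 6 fits that leave out an array.

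The genes with the largest rise included several enzymes and surface molecules beside the Notch and T cell genes. Mcpt1, a mast cell protease, rose 190-fold, from 3.18 ± 0.12 to 10.75 ± 0.33 (SD, n = 3), a fold change measured against a dim WT signal for which no detection call was used here. Khdc1a rose 160-fold, with N1IC arrays between 8.78 and 12.46. With sex as a covariate its log2 fold change was 7.39 against 7.32 without, and its adjusted p was 0.0796 by limma with Benjamini-Hochberg adjustment. Prss2, a trypsinogen, rose 85.9-fold, and all 4 of its probe sets rose, although related trypsinogen genes may share their signal. B4galnt2, a glycosyltransferase, rose 44.2-fold on its brightest probe set and in 3 of 4 probe sets overall. Cdh1, the adhesion molecule E-cadherin, rose 42.5-fold, Adamdec1, a metalloprotease, 38.2-fold, Gzmb, the cytotoxic protease granzyme B, 28.8-fold, Scin, an actin-severing protein, 19.4-fold, and Mpzl2, an adhesion molecule, 16.9-fold.

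**Figure D2:**
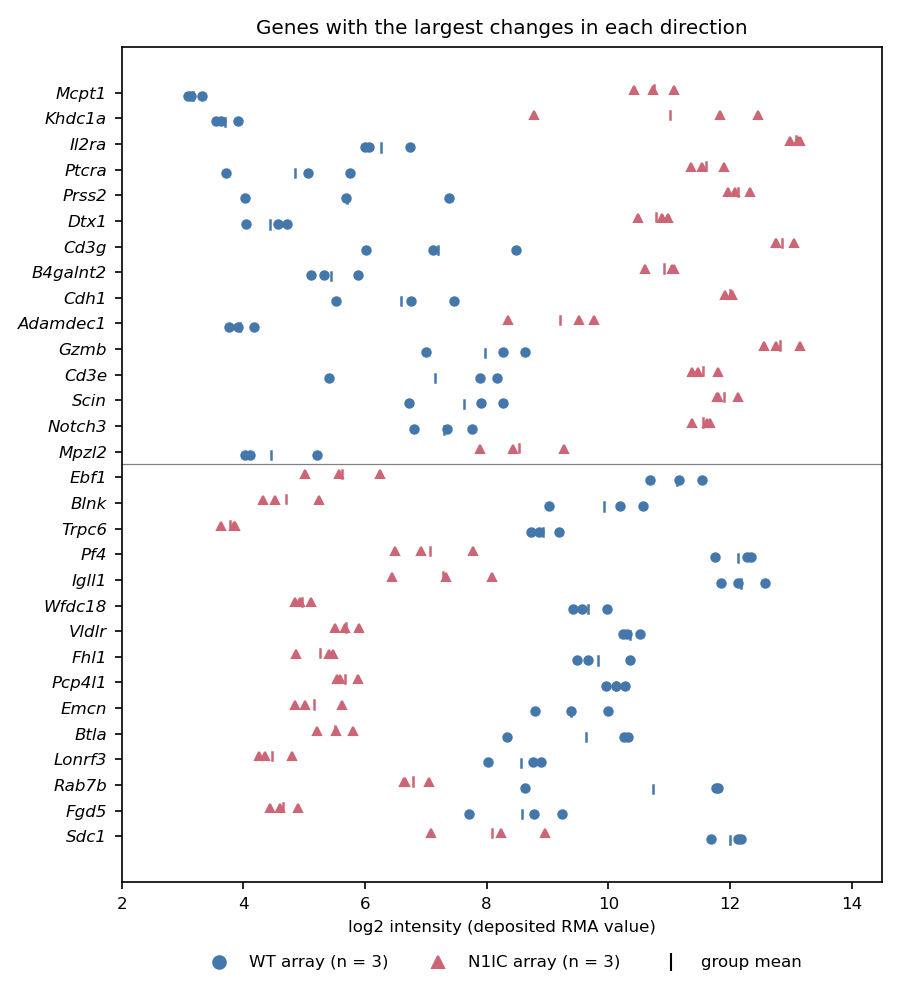
Log2 intensity (horizontal axis) on each WT array (circles, n = 3) and each N1IC array (triangles, n = 3) for the 15 genes with the largest rise and the 15 with the largest fall, with group means as short bars. The groups do not overlap for any of these genes, and Mcpt1 shows the widest distance, 3.18 against 10.75.

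Among the 13 measured Notch target genes, 11 rose and none fell, over all genes and also adjusted over the list alone. Hes1, a transcriptional repressor and direct target of Notch, rose 13.4-fold, from 8.15 ± 0.44 to 11.89 ± 0.16 (SD, n = 3). Dtx1, a ubiquitin ligase of the Notch pathway, rose 81.3-fold, Notch3 rose 19.0-fold and the transcription factor Gata3 rose 6.39-fold. Myc and Hes5, named after their values were seen, did not pass the test, with log2 fold changes of 0.02 and 0.26. The mean log2 fold change of the list was 3.23, with an adjusted p of 9.67e-15 by camera with Benjamini-Hochberg adjustment over the 21 lists. This call held with an estimated correlation (adjusted p = 0.0316 with an estimated correlation), the only one of the 10 lists called that did.

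The 26 measured components of the Notch pathway showed no common direction, with 2 higher and 3 lower over all genes and the same numbers adjusted over the list alone. Notch1 rose 1.66-fold on its brighter probe set, from 12.19 ± 0.16 to 12.93 ± 0.11 (SD, n = 3), with an adjusted p of 0.0119 by limma with Benjamini-Hochberg adjustment. A dimmer Notch1 probe set rose 2.65-fold. Where these probe sets lie relative to the N1-IC transgene is not known here, so Notch1 does not by itself check the labels. Mfng, Numb and Lfng, which modify or restrain Notch signalling, fell by 0.74, 0.49 and 0.48 on the log2 scale. Of 2 Lfng probe sets only 1 went in this direction, and neither passed with each probe set tested on its own. Without WT replicate 3, N1IC replicate 2 or N1IC replicate 3, 1 component was lower, and with sex as a covariate or female mice only none was lower and 1 was higher. The adjusted p of the list was 0.423 by camera with Benjamini-Hochberg adjustment, with a mean of 0.02 and a median of -0.11. Ncstn, a gamma-secretase subunit that the labels' treatment text names in place of N1-IC, stood at a log2 fold change of -0.28 ± 0.16 (SE, n = 3), with an adjusted p of 0.345 by limma with Benjamini-Hochberg adjustment.

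Of 21 measured T-lineage genes, 12 rose and none fell over all genes, while 14 rose and 1 fell adjusted over the list alone. Genes of the CD3 complex, which carries the signal of the T cell receptor, were among them, with Cd3g 50.3-fold and Cd3e 21.1-fold higher. Cd5, a surface molecule of T cells, rose 9.65-fold and the adaptor Lat rose 3.43-fold, from 10.32 ± 0.04 to 12.10 ± 0.02 (SD, n = 3). The coreceptor genes Cd4, Cd8a and Cd8b1, named after their values were seen, did not pass over all genes, with log2 fold changes of -0.62, -1.18 and 0.98. Cd8a differed between arrays of a group, at 9.61, 6.73 and 6.43 in N1IC and 6.95, 9.79 and 9.59 in WT. Cd8b1 stood at 7.16, 4.58 and 4.49 in N1IC and at 4.04, 5.01 and 4.24 in WT. Both were thus highest among N1IC arrays on N1IC replicate 1. With sex as a covariate 7 T-lineage genes rose, as many as without N1IC replicate 1, and 8 rose without N1IC replicate 2. The list also holds 3 of the measured Notch target genes. Its mean log2 fold change was 2.34, with an adjusted p of 8.69e-12 by camera with Benjamini-Hochberg adjustment, and the call was lost with a correlation taken from the data (adjusted p = 0.148 with an estimated correlation). The call of Cd3e was lost in each fit that left out 1 N1IC array, with adjusted p between 0.0516 and 0.0579 by limma with Benjamini-Hochberg adjustment.

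**Figure D3:**
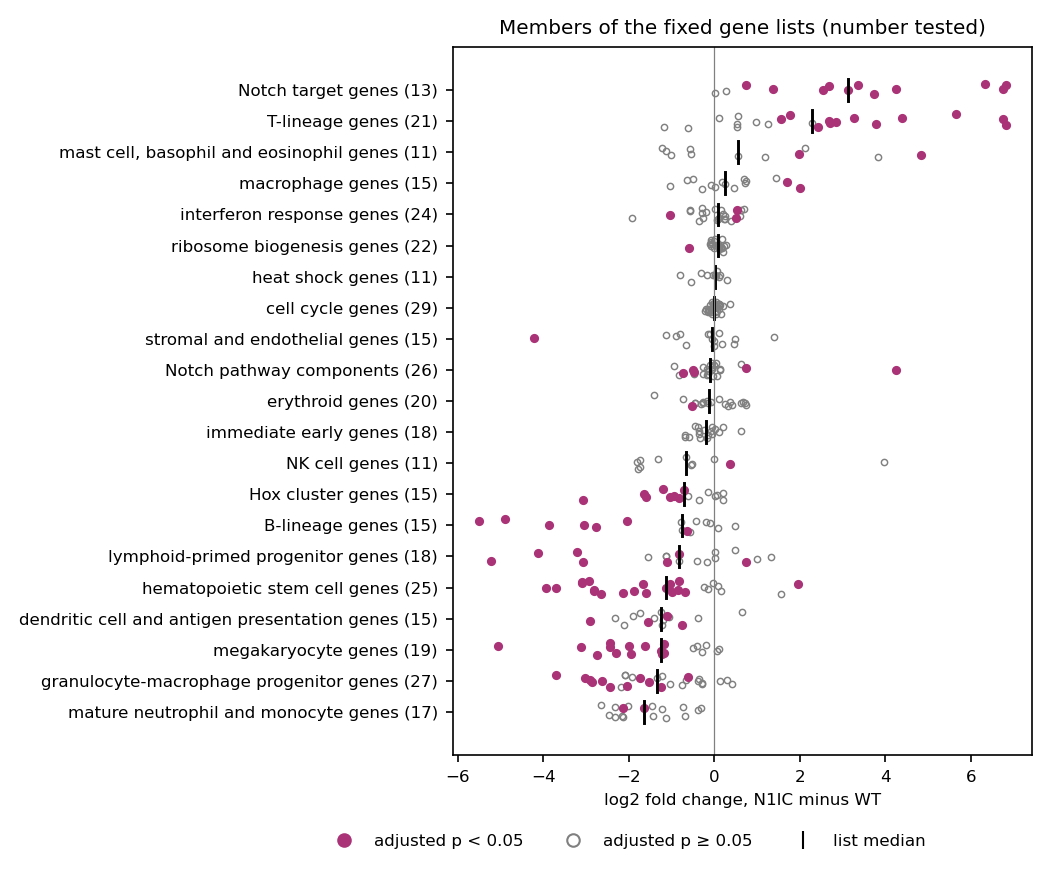
Log2 fold change, N1IC minus WT (horizontal axis), of each measured member of the 21 fixed gene lists (vertical axis, number of members in brackets); each point is 1 gene, filled where its adjusted p over all genes passed the threshold, and the bars are list medians. The Notch target list has the highest median, 3.13, and the mature neutrophil and monocyte list the lowest, -1.65.

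Of 25 measured hematopoietic stem cell genes, 18 fell and 1 rose over all genes, while 18 fell and 2 rose adjusted over the list alone. Fgd5, a guanine nucleotide exchange factor and marker of stem cells, was 15.3-fold lower. Hlf and Mecom, transcription factors of stem cells, were 8.51-fold and 7.02-fold lower, and Meis1, a partner of Hox proteins, was 3.70-fold lower, at 8.09 ± 0.09 against 9.98 ± 0.22 (SD, n = 3). The endothelial and stem cell receptor Robo4 was 8.53-fold lower. The member that rose was Thy1, named after its value was seen, which is also a surface molecule of T cells, with a log2 fold change of 1.96. With sex as a covariate 5 genes of this list fell and none rose, with female mice only 8 fell and 1 rose, and with 1 array left out 12 to 14 fell, with none higher when the array was from N1IC. The mean log2 fold change of the list was -1.38, with an adjusted p of 1.35e-08 by camera with Benjamini-Hochberg adjustment (adjusted p = 0.107 with an estimated correlation). Among 15 measured genes of the Hox clusters, which encode homeodomain transcription factors, 8 fell over all genes and 9 adjusted over the list alone. Hoxa10 was 8.37-fold, Hoxb3 3.15-fold and Hoxa9 2.07-fold lower. Without WT replicate 3, 4 Hox genes fell, without N1IC replicate 3, 5, with sex as a covariate 1, and with female mice only 2. The adjusted p of this list was 0.000544 by camera with Benjamini-Hochberg adjustment (adjusted p = 0.182 with an estimated correlation).

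Of 19 measured megakaryocyte genes, 13 fell and none rose over all genes, and 14 fell adjusted over the list alone. Beside Pf4, Treml1, a receptor of platelet granules, was 6.76-fold lower, Ppbp, a platelet chemokine, 5.46-fold lower, and Gp9, a subunit of the receptor for von Willebrand factor, 4.01-fold lower. Without WT replicate 3, 8 genes of this list fell, with sex as a covariate 6, and with female mice only 4. The mean log2 fold change of the list was -1.57, with an adjusted p of 1.51e-08 by camera with Benjamini-Hochberg adjustment (adjusted p = 0.107 with an estimated correlation). The 20 measured erythroid genes gave another picture, with 1 gene lower over all genes and none adjusted over the list alone. That gene was Car2, a carbonic anhydrase, which fell by 0.53 on the log2 scale, a call lost with sex as a covariate, with female mice only and in each fit that left out an array other than N1IC replicate 1, although 1 other erythroid gene fell without WT replicate 1, and 1 with female mice only. The mean of the erythroid list was -0.03 and its median -0.11, while the direction of camera was upward, with an adjusted p of 0.897 after Benjamini-Hochberg adjustment.

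Of 27 measured granulocyte-macrophage progenitor genes, 11 fell and none rose over all genes, and 17 fell adjusted over the list alone. Csf3r, the receptor for granulocyte colony-stimulating factor, was 13.0-fold lower, at 5.95 ± 0.33 against 9.65 ± 0.21 (SD, n = 3). The myeloid transcription factors Irf8 and Cebpa were 7.58-fold and 7.29-fold lower, and Lyz2, the gene of lysozyme, 3.36-fold lower. Without WT replicate 1, 17 genes of this list fell, without WT replicate 3, 7, with sex as a covariate 4, and with female mice only 5. The list had a mean log2 fold change of -1.43 and an adjusted p of 1.03e-07 by camera with Benjamini-Hochberg adjustment (adjusted p = 0.447 with an estimated correlation). Genes of mature neutrophils and monocytes, cells that the gate should remove, were measured beside it. Of 17 such genes, 2 fell over all genes and also adjusted over the list alone, Cd14 by 2.15 and Cxcr2 by 1.65 on the log2 scale. The mean of that list was -1.61 with an adjusted p of 0.000248 by camera with Benjamini-Hochberg adjustment (adjusted p = 0.6 with an estimated correlation), and its genes also varied among WT arrays, as Mmp8, named after its values were seen, did, at 6.53, 10.27 and 10.08. Without WT replicate 1, the lowest of these for Mmp8, 14 of the 17 genes fell, and without WT replicate 2 or 3, or without N1IC replicate 1 or 2, 1 fell.

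Of 15 measured B-lineage genes, 7 fell and none rose, over all genes and adjusted over the list alone. Igll1 and Vpreb1, which form the surrogate light chain of the pre-B cell receptor, were 29.8-fold and 6.80-fold lower, and Cd79a, a signalling chain of that receptor, was 14.7-fold lower. The mean log2 fold change of the list was -1.67 and the adjusted p 2.02e-05 by camera with Benjamini-Hochberg adjustment (adjusted p = 0.107 with an estimated correlation). Of 18 measured genes of lymphoid-primed progenitors, 6 fell and 1 rose over all genes, and 8 fell and 2 rose adjusted over the list alone. With sex as a covariate 4 of them fell and none rose, and with female mice only 3 fell and none rose. The adaptor Blnk was 37.8-fold, the inhibitory receptor Btla 17.4-fold and the receptor tyrosine kinase Flt3 8.47-fold lower, while Notch1 was the member that rose. With female mice only 3 genes of the list fell, with sex as a covariate 4, and none rose in either fit. This list had a mean of -1.07 and an adjusted p of 0.0155 by camera with Benjamini-Hochberg adjustment (adjusted p = 0.6 with an estimated correlation). With only the brighter 60% of genes its adjusted p was 0.0859.

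Of 15 measured dendritic cell and antigen presentation genes, 4 fell over all genes and 8 adjusted over the list alone. Xcr1, a chemokine receptor of dendritic cells, was 7.50-fold lower, and the transcription factor Irf4 2.92-fold lower. WT replicate 1 stood apart from the other WT arrays on this list, with Xcr1 at 5.45 against 7.89 and 7.83 and Siglech at 6.90 against 9.22 and 9.23. Without WT replicate 1, 12 of the 15 genes fell, without any other single array 1 or 2, with sex as a covariate none, and with female mice only 8. The list had a mean of -1.35 and an adjusted p of 0.000145 by camera with Benjamini-Hochberg adjustment (adjusted p = 0.6 with an estimated correlation). The remaining genes with the largest falls belonged to no list of a blood lineage. Trpc6, a cation channel, was 35.4-fold lower, Vldlr, a lipoprotein receptor, 25.4-fold, and Emcn, an endothelial sialomucin, 18.7-fold. Sdc1, a heparan sulfate proteoglycan, fell by 3.91 on the log2 scale. Wfdc18 was 25.9-fold, Fhl1 23.9-fold, Pcp4l1 21.9-fold and Lonrf3 17.1-fold lower. Rab7b, a small GTPase, was 15.4-fold lower, with WT arrays between 8.63 and 11.80, and its call was lost when any single array other than WT replicate 1 was left out, with adjusted p between 0.101 and 0.112 by limma with Benjamini-Hochberg adjustment.

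With all 6 arrays, all genes, the deposited normalization, no covariate and no intensity trend, lists of other cells and general processes did not pass the camera test. Of 11 measured mast cell, basophil and eosinophil genes, 2 rose over all genes and 3 adjusted over the list alone, among them Cpa3, a mast cell carboxypeptidase, by 3.93-fold, and Gzmb. Of 15 macrophage genes, 2 rose over all genes and 3 adjusted over the list alone, with the complement genes C1qb and C1qc 4.03-fold and 3.27-fold higher. Of 11 NK cell genes, Nkg7 rose 1.29-fold over all genes, and 2 rose adjusted over the list alone. Of 15 stromal and endothelial genes only Emcn changed, while 3 fell without WT replicate 1 or with female mice only, and 2 without N1IC replicate 3 or with an intensity trend. The adjusted p of these 4 lists by camera with Benjamini-Hochberg adjustment was 0.123, 0.052, 0.479 and 0.582. The camera calls of the first 3 lists depended on single arrays. The NK cell list was called lower without WT replicate 1 (mean -1.22, adjusted p 0.00705 by camera with Benjamini-Hochberg adjustment), the mast cell list higher without WT replicate 2 or 3 (1.63 and 1.21, adjusted p 0.0145 and 0.0362), and the macrophage list higher without WT replicate 2 or N1IC replicate 1 or 2 (0.48, 0.49 and 0.49, adjusted p 0.0121, 0.031 and 0.0189). No single macrophage gene was called without WT replicate 3, with sex as a covariate or with female mice only, and Nkg7 was called in none of these fits nor in any that left out 1 array. With female mice only, 3 mast cell, basophil and eosinophil genes rose and 4 fell. The macrophage list also passed after a repeated quantile normalization and with an intensity trend, and the mast cell list among the brighter 40% of genes.

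None of 29 cell cycle genes passed by limma over all genes or adjusted over the list alone, although 1 rose and 2 fell with an intensity trend, and Pcna, a DNA polymerase clamp, stood at 13.45 ± 0.05 in N1IC against 13.50 ± 0.03 in WT (SD, n = 3). Of 22 ribosome biogenesis genes only Cad, an enzyme of pyrimidine synthesis, changed, and it fell by 0.60 on the log2 scale, a call lost with sex as a covariate, with female mice only and in each fit that left out an array other than N1IC replicate 2. Of 24 interferon response genes, Oasl1 and Gbp2 rose 1.45-fold and 1.41-fold and Ifi27l2a fell by 1.04 on the log2 scale, while 2 rose and 2 fell adjusted over the list alone. No interferon response gene was called with sex as a covariate or with female mice only, and Ifi27l2a was not called without WT replicate 2 or 3 or N1IC replicate 2 or 3. None of 18 immediate early and 11 heat shock genes passed over all genes or adjusted over the list alone, with log2 fold changes of -0.34 for Fos and -0.03 for Hspa8, although 1 immediate early gene fell without WT replicate 2 and 1 heat shock gene without WT replicate 1 and with female mice only. The adjusted p by camera with Benjamini-Hochberg adjustment was 0.729 for cell cycle, 0.201 for ribosome biogenesis, 0.423 for interferon response, 0.423 for immediate early and 0.678 for heat shock genes.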

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

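The tests of dilution and of a loss of signal, and the test of sex over genes that differ at least 2-fold, were chosen after the results were seen, as was the list of mature T cell genes. The other tests were set before the result they measure. Among 9160 probe sets with no gene symbol, which the comparison of genes did not use, 275 were higher and 167 lower in N1IC by limma, with log2 fold changes between -4.64 and 4.81.

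T-lineage genes were higher in N1IC. If mature T cells in the sorted fraction brought these transcripts, their other abundant genes would rise too. Over 12 genes of mature T cells outside the T-lineage list the median log2 fold change was 0.17, with an exact sign-test interval from -0.36 to 0.66. This median does not decide the question, because most of these genes were already bright in WT, such as Klf2 at 12.17 and Ms4a6b at 11.33. The interval also treats the genes as independent. Among the members with a WT mean under 8, Ccr7 fell by 1.10, S1pr1 stood at 0.19, Icos at 0.29 and Cd40lg at -0.05, while Skap1 rose 6.54-fold. These genes are too few to decide. Ccr7 is also on the dendritic cell and lymphoid-primed lists, and Cd40lg was dim in both groups, at 5.00 in WT and 4.95 in N1IC. Among mature T cell genes left out as T-lineage members, Cd28 and Cd6 rose 6.49-fold and 2.96-fold, while Cd4, Cd8a and Cd8b1 did not pass. Of 20 genes of double-negative thymocytes, which lack Cd4 and Cd8, 12 rose and 1 fell, with a mean of 2.60. This list was chosen after the data were examined and not cleared of T-lineage members. Its adjusted p was 1.47e-10 by camera with Benjamini-Hochberg adjustment over the added lists (0.196 with an estimated correlation). The double-positive thymocyte list did not pass (0.134 by the same test). Mature T cells, immature T-committed cells inside the gate and a change within the progenitors themselves all stay open, since sorted bulk RNA does not separate them. An effect of genotype on any of them is a hypothesis.

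Stem cell, megakaryocyte and granulocyte-macrophage genes were lower in N1IC. The median over 8919 bright genes outside the lists was -0.0287, which says nothing on a loss of signal over whole N1IC arrays, because normalization had brought the arrays to nearly 1 distribution (quartiles within 0.0556 on the log2 scale). Dilution of unchanged LSK cells by a T-committed population would lower erythroid genes as far as stem cell genes. The median of 15 bright erythroid genes was 0.95 above that of 21 bright stem cell genes (-0.18 against -1.14, permutation test, p = 0.0222). The permutation treats genes as independent, while the erythroid list had an estimated correlation of 0.509, so its p does not measure the spread between mice. The difference falls between the limits set for this test. Dilution may therefore account for part of the fall and cannot be told apart from a change within the cells. A variant that compared only stem cell, megakaryocyte and granulocyte-macrophage genes already called lower was also run and set aside, because genes picked for their fall must lie below unselected ones. Some granulocyte-macrophage genes also varied among WT arrays. Irf8 stood at 11.28, 12.83 and 12.69, lowest on WT replicate 1 as Mmp8 was, while Csf3r stood at 9.48, 9.58 and 9.88. Whether mature cells in WT samples added to the fall of this list was not tested.

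The count of 2144 genes was set against sex and chance. The first test of sex, over called genes, gave a median ratio of 0.0743 between the WT female's distance from the WT males and the change with genotype. It decides nothing, because calling favours genes with little spread among WT arrays, and Xist itself was not called (adjusted p = 0.162, limma with Benjamini-Hochberg adjustment). Over 1449 genes off the X and Y chromosomes that differ at least 2-fold, called or not, the ratio was 0.0594. Its bootstrap interval, taken over genes, ran from 0.0364 to 0.0777, where a pure sex effect gives 1.5. The ratio rests on WT replicate 2 as the only WT female, and the interval does not measure the spread between mice. Within that limit the ratio argues against sex as the source of most of these differences, but not for any single gene. Of the 10 splits of the arrays into 3 and 3, only the real one (1 of 10) gave 2144 genes and the highest other gave 1, and 10 splits are too few to reach a share under 0.05.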

How the results depend on the processing

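Of the 2144 called genes, those tested kept their direction (all 2144 in most alternatives, 1800 among the brighter 60% of genes, 908 among the brighter 40% and 2059 without X and Y), except with the mean of all probe sets, where 2123 did. Because the groups do not overlap for any called gene, most of these alternatives could not have changed a direction. Only new values, from the mean of all probe sets or another normalization, could have done so. Single probe sets were not matched to these genes. The counts of higher and lower genes were 116 and 333 with sex as a covariate (409 of the calls kept), 142 and 504 with female mice only, chosen after the data were examined (473 kept), and 289 and 768 with a 2-fold minimum. The fits with sex as a covariate and with female mice only set the N1IC arrays against WT replicate 2, the only WT female. The fewer calls in these fits therefore do not measure an effect of sex. Only 857 genes were lower among the brighter 40% of genes, where fewer genes were tested. At an adjusted p under 0.1, 1038 genes were higher, and with each probe set on its own 1422 probe sets were. Leaving out 1 array gave between 332 and 509 higher and between 835 and 1420 lower genes, with fewer samples. The replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at -0.0884, -0.0934 and 0.0956, and the replicate block gave 357 higher and 936 lower genes.

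With an estimated correlation camera no longer called 9 of 10 lists, among them granulocyte-macrophage (mean -1.43), megakaryocyte (-1.57), stem cell (-1.38), lymphoid-primed (-1.07) and T-lineage genes (2.34). A high correlation was not needed for such a loss. The B-lineage list had an estimated correlation of 0.0273, near the preset 0.01, yet its p by camera before adjustment went from 5.77e-06 to 0.0146. This form of camera uses only the 4 residual degrees of freedom. The lymphoid-primed call was also lost among the brighter 60% (-1.07) and 40% (-0.35) of genes, with the mean of all probe sets (-0.86), and without WT replicate 2 or 3 (range over arrays left out -1.32 to -0.93). The cause was not tested for this or for the changes of sign that follow. The directional test of fry also ended the calls of the mature neutrophil and the dendritic cell lists, with adjusted p of 0.182 and 0.0848. The same test kept the other calls. Its adjusted p was 3.28e-05 for Notch target, 0.00121 for T-lineage, 0.00113 for stem cell and 0.00121 for megakaryocyte genes. It was 0.00111 for B-lineage, 0.021 for granulocyte-macrophage, 0.0369 for lymphoid-primed and 0.00275 for Hox genes. The mixed test of fry, for changes in either direction, passed for 7 lists that camera did not call. Its adjusted p was 3.97e-09 for Notch pathway, 6.65e-06 for interferon response, 8.37e-05 for stromal and 0.000205 for ribosome biogenesis genes. It was 0.000205 for mast cell, 0.0106 for cell cycle and 0.023 for NK cell genes, and 0.0628 for the mature neutrophil list, which did not pass.

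The erythroid mean was 0.004 among the brighter 60% of genes, 0.064 among the brighter 40%, 0.01 with the mean of all probe sets, 0.02 without genes of X and Y, and between -0.26 and 0.16 with 1 array left out. With sex as a covariate and with female mice only, the mast cell list stood at -0.53, interferon response at 0.006 and Hspa8 at 0.02. Both fits rest on WT replicate 2 as the only WT female. Hspa8 was 0.17 with the mean of all probe sets. The NK cell list was -1.22 without WT replicate 1 and -1.36 with female mice only, called lower in both (adjusted p 0.00705 and 0.00595), but 0.38 among the brighter 60% and 0.91 among the brighter 40%, where cell cycle was -0.008, interferon response 0.14 and heat shock 0.057. Cell cycle was -0.006 after a repeated quantile normalization. Calls were gained by the macrophage list after that normalization and with an intensity trend (adjusted p 0.0424 and 0.0483) and by the mast cell list among the brighter 40% (1.86, 0.0429), beside those with 1 array left out. With 1 array left out the ranges were -0.11 to 1.63 for mast cell, -0.005 to 0.015 for cell cycle, -0.013 to 0.037 for Notch pathway, -0.48 to 0.11 for heat shock, -0.16 to 0.054 for interferon response and -0.46 to 0.16 for immediate early genes, -0.21 to 0.035 for Jund and -0.34 to 0.13 for Dusp1. Signal over background limits dim genes, for which no detection call was used here.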

Other observations

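All lists and genes in this part were chosen after the data were examined, and limma with Benjamini-Hochberg adjustment over all genes was used. Of 8 Gimap genes, a family of GTPases of lymphocytes, 4 fell and 1 rose, with Gimap8, Gimap3, Gimap4 and Gimap6 lower by log2 fold changes of -2.22, -1.99, -1.67 and -0.93 and Gimap9 higher by 0.47. Among 6 guanylate binding proteins, Gbp8, Gbp6 and Gbp2 rose 5.25-fold, 3.42-fold and 1.41-fold. Among 23 cytokine receptor genes 3 rose and 7 fell, with Il17rb 8.28-fold higher and Tnfrsf1a 2.56-fold lower. Of 42 collagen genes 3 rose and 3 fell: Col4a1, Col4a2 and Col16a1 were 6.63-fold, 12.2-fold and 2.07-fold lower, and Col18a1, Col15a1 and Col9a3 were 5.90-fold, 4.03-fold and 3.81-fold higher. Among 41 claudin and cadherin genes 3 rose and 4 fell, with Cldn2 15.4-fold, Cldn10 10.1-fold and Cdh1 42.5-fold higher and Cdh2 7.56-fold, Cldn12 3.61-fold, Cldn7 1.88-fold and Cdh11 1.76-fold lower. For scale, 2144 of all 18193 genes tested were called. By camera with Benjamini-Hochberg adjustment over the added lists, the Gimap list was lower (adjusted p = 0.0172) and the guanylate binding list higher (adjusted p = 0.00615). The cytokine receptor, collagen, and claudin and cadherin lists did not pass (adjusted p = 0.0643, 0.76 and 0.7005). With an estimated correlation none of these lists passed, at 0.494, 0.541, 0.541, 0.823 and 0.747 in the same order.

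Mcpt1 and Gzmb lie in the chymase and granzyme gene cluster on chromosome 14 in the RefSeq gene table. Of 14 measured genes from Cma1 to Gzmb, Mcpt1, Gzmb and the pseudogene Mcpt-ps1 (3 genes) rose and none fell, and 11 did not pass. Among those, log2 fold changes ran from -1.04 for Ctsg and -0.56 for Mcpt8 to 2.13 for Cma1, 3.04 for Gzmc, 3.84 for Mcpt4 and 4.57 for Mcpt2. Prss2 lies between the T cell receptor beta segments Trbv30 and Trbd1 in the same table, and the segment Trbv13-2 rose by 3.12. Eosinophil and mast cell genes varied widely within WT, as Prg2 did, at 3.88, 13.35 and 11.36 on the 3 WT arrays.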
